A study of Mus musculus with 45 samples.

How the data were processed

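RNA was measured by sequencing in nucleus accumbens punches from 45 female mice of the HDID-1 line. Per the labels, every mouse received 2 viruses (0.5 uL of each) on both sides of the nucleus accumbens, a Cre-GFP virus and a Cre-dependent hM3Dq-mCherry virus. hM3Dq is an engineered human muscarinic receptor that is activated by clozapine N-oxide (CNO). Mice drank alcohol or water daily for 6 weeks. They received vehicle in week 1, CNO at 1 mg/kg or vehicle in weeks 2 to 5, and vehicle again in week 6. Libraries were made from 500 ng of RNA with an Illumina TruSeq protocol.

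The deposited files hold counts: whole numbers of reads per gene symbol, 1 file per library, with no normalization. Per the labels the authors used FastQC, STAR and HTSeq 0.9.1 with the GRCm38 (mm10) build. The STAR version, the annotation, the strand setting and the counting mode are not given in the sources used here. Each file lists 24421 gene symbols followed by HTSeq's 5 summary rows, which were kept apart from the genes and used as library measures.

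Groups were taken from the labels: alcohol with CNO (12 mice), alcohol with vehicle (11), water with CNO (11) and water with vehicle (11). Each library is a different mouse and nothing in the labels pairs mice across groups, so no paired analysis was made. Tube numbers in the sample titles run from 1 to 24 for alcohol drinkers and from 25 to 46 for water drinkers, so tube order and fluid cannot be separated. The S numbers in the titles were read as 8 consecutive blocks. That reading was inferred from the titles and is not stated in them, and each block spans alcohol and water mice.

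Genes were filtered with filterByExpr by group, which left 15852, and scaled by TMM. A quasi-likelihood model (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust fitting) with 1 coefficient per group was fitted to all 45 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are approximations, the size of the fold change divided by the square root of the F statistic. Levels are in CPM after TMM scaling, and log2 CPM used a prior count of 2. Every adjusted p of a single gene comes from edgeR unless another tool is named.

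There were 7 contrasts: alcohol under vehicle, CNO in alcohol drinkers, CNO in water drinkers, alcohol under CNO, the interaction, alcohol averaged over treatments and CNO averaged over fluids. The contrasts, the threshold, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule named, for each contrast other than the averaged ones, the 10 higher and the 10 lower genes with the smallest p among those that passed with a mean log2 CPM of at least 0. For the averaged contrasts it named the first 5 in each direction. Where fewer than 10 passed, it named the 10 genes with the smallest p. It added the 3 members with the smallest p of each list that passed its test, and 9 genes of the region in every contrast: Chrm3, Drd1, Drd2, Pdyn, Penk, Tac1, Fos, Bdnf and Gfap. Genes named outside this rule are said to be chosen after their values were seen.

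Of 37 gene lists of cell type markers and pathways, 36 had at least 3 tested members. Lists were tested with camera (limma 3.58.1) on voom-transformed counts with a preset correlation of 0.01. The same test with the correlation estimated from the data and the directional fry test were run beside it. A list score is the mean log2 CPM of its tested members in a library. Scores were compared between groups by two-sided permutation tests with 100000 permutations (Python 3.11.15, numpy 2.4.6, scipy 1.17.1), adjusted over 164 tests.

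The pipeline was tested on simulated data made from these libraries, with 50 genes changed at each fold. At a 2-fold change it recovered 96% of the genes for alcohol under vehicle, 90% for CNO in alcohol drinkers, 96% for CNO in water drinkers, 94% for alcohol under CNO and 82% for the interaction. At 1.25-fold it recovered 54%, 46%, 58%, 68% and 44% in the same order. False calls among unchanged genes numbered 7, 10, 7, 7 and 4. The simulated genes were drawn independently of each other and held no outlying libraries. The recovery therefore does not extend to genes that move together or that are extreme in a few mice.

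The first set of alternatives was DESeq2-style size factors, no filter, a filter at a mean CPM of 1, S-number block as a covariate, surrogate variables (sva 3.50.0, 5 used), 7 outlying libraries left out, counts thinned to the smallest library, DESeq2 1.42.0, voom with sample weights, an adjusted p under 0.1, and fits of only the groups compared. Alternatives chosen after seeing the data left out alcohol vehicle replicates 5 and 10, called immune-rich here, which had the highest scores on the first principal component and high levels of MHC class II and antibody genes. Others also left out water vehicle replicate 9, left out each library in turn, or used as a covariate the no-feature share (the percentage of uniquely aligned reads in no annotated gene), log2 Chrm3 CPM, or the mean of 1 of 3 marker lists. Groupings of the libraries drawn at random, 100 per contrast with the real one included, were fitted in the same way.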

Results

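RNA sequencing of the nucleus accumbens compared alcohol and water drinkers that had received CNO or vehicle. There were 12 alcohol CNO, 11 alcohol vehicle, 11 water CNO and 11 water vehicle libraries, each from 1 mouse. Reads assigned to genes ranged from 26.8 M to 39.5 M per library, with a mean of 32.1 M (SD 3.23 M, n = 45). On average 18455 gene symbols were detected per library. The first principal component of log2 CPM held 19.5% of the variance and the second 15.1%. Reads outside annotated genes made up 15.6% to 21.9% of the uniquely aligned reads.

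Markers of the neurons that make up most of the nucleus accumbens were expressed at high and similar levels in all groups. Drd1, the D1 dopamine receptor, had a mean of 243 CPM ± 31.7 (SD, n = 12) in alcohol CNO and 249 CPM ± 31.3 (n = 11) in alcohol vehicle mice. In water CNO mice Drd1 was at 230 CPM ± 28.6 (n = 11), and in water vehicle mice at 251 CPM ± 19.9 (n = 11). Drd2, the D2 dopamine receptor, lay between 118 and 127 CPM in the group means. Penk, the enkephalin precursor, was at 1079.5 CPM ± 138 in alcohol CNO mice, and Pdyn, the dynorphin precursor, at 299.8 CPM ± 36.5. None of Drd1, Drd2, Pdyn, Penk, Tac1, Fos, Bdnf or Gfap passed the edgeR threshold in any of the 7 contrasts. Cortical glutamatergic markers varied more between libraries. Their list score ran from 1.77 to 4.77, against 8.57 to 9.21 for the medium spiny neuron markers.

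The question whether CNO changed expression in mice that drank alcohol was addressed by comparing alcohol CNO with alcohol vehicle mice. Genes induced by interferon and genes of antigen presentation fell in the CNO mice. Cxcl10, a chemokine that attracts T cells, fell by 2.92 ± 0.58 on the log2 scale (SE, adjusted p = 0.00876). Its mean was 0.896 CPM ± 0.938 (SD, n = 12) with CNO and 6.72 CPM ± 8.8 (n = 11) with vehicle. Irf7, a transcription factor of the interferon response, fell by 2.13 ± 0.43 and Ccl5, a chemokine of T cells, fell by 3.47 ± 0.63. H2-Ab1, a chain of MHC class II, fell by 3.92 ± 0.79. Without alcohol vehicle replicates 5 and 10 its log2 fold change was -0.55. In that fit 0 genes passed in this comparison, so Cxcl10, Irf7, Ccl5 and H2-Ab1 all lost their calls.

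In all, 138 genes passed the threshold in alcohol drinkers and each of them was lower with CNO. Gm12250, Ifi47, Tgtp2 and Iigp1 of the interferon-induced GTPases fell by 3.36, 3.13, 3.40 and 2.66 on the log2 scale. Gbp10 fell by 4.07 ± 0.76, Cxcl13, a B cell chemokine, by 3.58 ± 0.70, Cxcl9 by 3.68 ± 0.72 and Slfn2 by 1.93 ± 0.36. Of the 19 listed interferon-induced genes 14 fell, and 19 fell when adjusted over the list alone, with a median log2 fold change of -1.54. Without alcohol vehicle replicates 5 and 10 and water vehicle replicate 9, 0 of the 19 passed and the median was -0.72. The list passed camera (adjusted p = 6.69e-33), with adjusted p = 0.0885 with an estimated correlation. Bst2, which tethers virus particles, fell by 1.99 ± 0.40, and Zbp1, a sensor of nucleic acids, by 2.65 ± 0.53.

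Of the 14 listed antigen presentation genes 12 fell in alcohol drinkers, and 14 fell when adjusted over the list alone, with a median of -1.86. The list had adjusted p = 0.165 with an estimated correlation. Cd74, the invariant chain of MHC class II, fell by 3.86 ± 0.80 and H2-Eb1 by 4.17 ± 0.87. Of the 14, 0 passed without alcohol vehicle replicates 5 and 10, where Cd74 had -0.59. Among 19 reactive astrocyte genes 4 fell over all genes and 14 when adjusted over the list alone (median -0.63, adjusted p = 0.165 with an estimated correlation). This list includes Cxcl10, named above with the interferon-induced genes. Without alcohol vehicle replicates 5 and 10, 0 of the 19 passed, and the list had adjusted p = 0.489 with an estimated correlation. Of this list Gbp2 fell by 1.94 ± 0.42 and Serping1, an inhibitor of complement, by 1.28 ± 0.32. Tissue punches do not show whether Gbp2 and Serping1 fell in astrocytes, or apart from the interferon-induced genes. Among 18 microglia markers 0 passed in edgeR over all genes and 5 when adjusted over the list alone, with a median of -0.22 and adjusted p = 0.446 with an estimated correlation. C1qa, a complement component, had a log2 fold change of -0.72 ± 0.22 (adjusted p = 0.128).

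The spread of these genes among alcohol vehicle mice was wide. H2-Aa, a chain of MHC class II, was at 263 CPM in replicate 5 and 62.1 CPM in replicate 10 of that group, whose median was 2.04 CPM. Jchain, a gene of antibody-producing cells chosen after its values were seen, was at 565 CPM and 145 CPM in the same libraries, against a group median of 25.6 CPM. The count of 138 became 0 without alcohol vehicle replicate 5, 51 without replicate 10, 240 without replicate 4, 220 without replicate 8, 230 without replicate 9, and 88 without alcohol CNO replicate 12. It was also 0 with S-number block as a covariate, with surrogate variables, in voom with sample weights, and in a fit of only the alcohol drinkers, while DESeq2 gave 179.

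**Figure D1:**
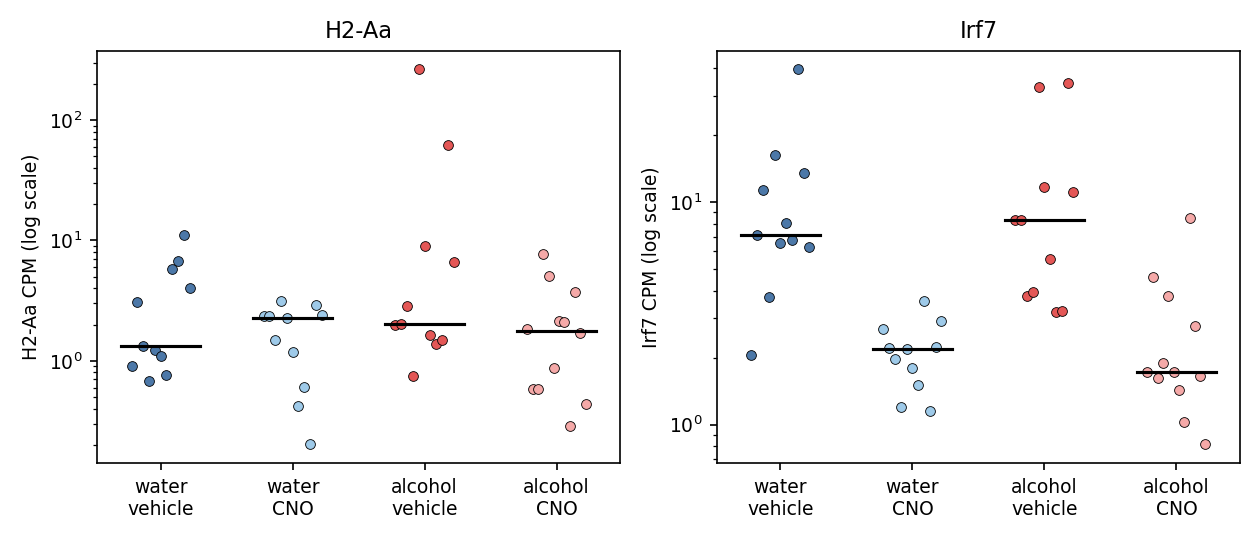
Levels of H2-Aa (left) and Irf7 (right) in each library, in CPM on a log axis, by group. Each point is 1 mouse and lines are group medians. H2-Aa reaches 263 CPM in 1 alcohol vehicle mouse against a median of 2.04 CPM in that group.

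The corresponding comparison in water drinkers asked whether CNO changed expression without alcohol. Interferon-induced genes again fell with CNO. Mx2, an interferon-induced GTPase, fell by 2.05 ± 0.35 on the log2 scale (SE, adjusted p = 0.00787) and Cxcl10 by 3.58 ± 0.64 (adjusted p = 0.0108). Isg15, a ubiquitin-like protein induced by interferon, had a mean of 2.31 CPM ± 0.715 (SD, n = 11) with CNO and 10.5 CPM ± 8.02 (n = 11) with vehicle. Irf7 fell by 2.36 ± 0.45, Mx1 by 2.73 ± 0.53, Ifit1 by 2.24 ± 0.45 and Usp18, a protease that removes Isg15, by 1.93 ± 0.41.

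In water drinkers 11 genes passed, all lower with CNO, and Oas1b, Oasl2 and Ifi44 were among them at -2.28, -2.33 and -2.20. Of the 19 listed interferon-induced genes 6 fell over all genes and 19 when adjusted over the list alone, with a median of -1.28. The list had adjusted p = 0.0584 with an estimated correlation and adjusted p = 0.0389 in fry. Of 14 antigen presentation genes 0 passed in edgeR, over all genes or adjusted over the list alone, with a median of -0.64 and adjusted p = 0.529 with an estimated correlation. The count of 11 became 1 without water vehicle replicate 9, 6 without water CNO replicate 3, 4, 5 or 9 or water vehicle replicate 5, and 7 without water CNO replicate 1, 2 or 7 or water vehicle replicate 3. It was 4 with S-number block as a covariate, 0 in voom with sample weights and 25 in DESeq2.

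Neuron, oligodendrocyte and oligodendrocyte precursor lists had medians near 0 in water drinkers. No neuron or glia list passed with an estimated correlation in the fit to all libraries. Without alcohol vehicle replicates 5 and 10 the microglia and reactive astrocyte lists were lower with CNO by camera (adjusted p = 2.13e-07 and 1.15e-05). Each had adjusted p = 0.314 with an estimated correlation. All 9 oligodendrocyte precursor markers had positive log2 fold changes with a median of 0.10 (camera adjusted p = 0.000105), and adjusted p = 0.0584 with an estimated correlation. None passed singly. Without alcohol vehicle replicates 5 and 10, which are not in the groups compared, this list had adjusted p = 0.0254 with an estimated correlation, and the interferon and lymphocyte lists, both lower with CNO, each had adjusted p = 0.00848. The lymphocyte list holds Ccl5, which interferon itself induces, and camera was not run without Ccl5. Of 15 oligodendrocyte genes 14 were positive, with a median of 0.15 and adjusted p = 0.41 with an estimated correlation. Of 16 medium spiny neuron markers 15 were negative, with a median of -0.08 and adjusted p = 0.529 with an estimated correlation.

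The mice of both fluids together gave the comparison of CNO with vehicle averaged over fluids. Cxcl10 fell by 3.25 ± 0.43 on the log2 scale (adjusted p = 3.35e-05), Irf7 fell by 2.25 ± 0.31, Ccl5 by 3.22 ± 0.46, Isg15 by 1.95 ± 0.28 and Oasl2 by 2.19 ± 0.33. Of 141 genes that passed, 137 fell and 4 rose. The 4 that rose were Slc17a5 (0.10 ± 0.02), Tbc1d9b (0.12 ± 0.03), Dclre1a (0.16 ± 0.04) and Ttll5 (0.10 ± 0.03). All 19 interferon-induced genes fell, over all genes and adjusted over the list alone, with a median of -1.41. This list held with an estimated correlation (adjusted p = 0.0113) and in fry (adjusted p = 0.0012). Of 6 lymphocyte markers 1, which was Ccl5, fell over all genes and 4 when adjusted over the list alone (median -0.41, adjusted p = 0.124 with an estimated correlation). Cd2 had -0.93 ± 0.30 and Lck -0.40 ± 0.13. With the lymphocyte score as a covariate 0 of the 19 interferon-induced genes passed, and 12 passed with that score computed without Ccl5.

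Averaged over fluids, 10 of 14 antigen presentation genes fell over all genes and 14 when adjusted over the list alone, with a median of -1.22 and adjusted p = 0.147 with an estimated correlation. Only 2 of the 14 passed without alcohol vehicle replicates 5 and 10. In the fit to all libraries H2-T23 fell by 1.38 ± 0.28, H2-K1 by 1.40 ± 0.33 and Cd74 by 2.38 ± 0.56. Gbp2, a member of the reactive astrocyte list, fell by 1.26 ± 0.30 (adjusted p = 0.022). In tissue punches its fall cannot be assigned to astrocytes or told apart from that of the interferon-induced genes. The microglia markers C1qa, Ctss and C1qc had -0.56, -0.55 and -0.48 (adjusted p = 0.0814, 0.109 and 0.122). Without alcohol vehicle replicates 5 and 10 the microglia and reactive astrocyte lists were lower by camera (adjusted p = 0.000102 and 9.13e-09). With an estimated correlation they had adjusted p = 0.704 and 0.174. Neither list was used as a covariate. The count of 141 became 73 without the same 2 libraries, and without those and water vehicle replicate 9 it was 61, of which 17 were listed interferon-induced genes. With surrogate variables it was 7, without the 7 outlying libraries 24 and in voom 47, whereas with S-number block as a covariate it was 120.

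**Figure D2:**
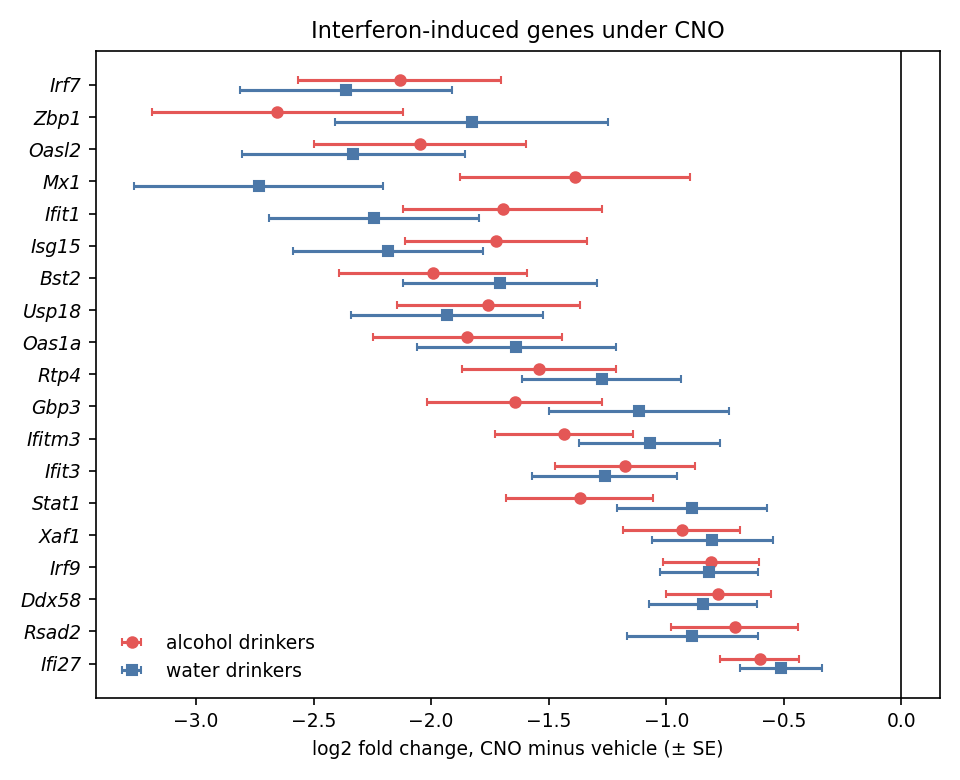
Log2 fold change (CNO minus vehicle, with SE) of the 19 listed interferon-induced genes in alcohol drinkers (circles) and water drinkers (squares). All 19 are below 0 in both fluids, with medians of -1.54 and -1.28, against -0.72 and -1.07 without alcohol vehicle replicates 5 and 10 and water vehicle replicate 9.

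The interferon score of each library, the mean log2 CPM of the 19 genes, was 1.98 ± 0.57 (SD, n = 12) in alcohol CNO and 3.15 ± 1.03 (n = 11) in alcohol vehicle mice. This difference of -1.17 had a permutation p of 0.00118 and an adjusted p of 0.0645 over 164 tests, with 11 of 12 CNO mice below the vehicle median. In water drinkers the score was 1.86 ± 0.31 (n = 11) with CNO and 3.10 ± 0.85 (n = 11) with vehicle. That difference of -1.24 had an adjusted permutation p of 0.0115, and all 11 CNO mice were below the vehicle median.

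**Figure D3:**
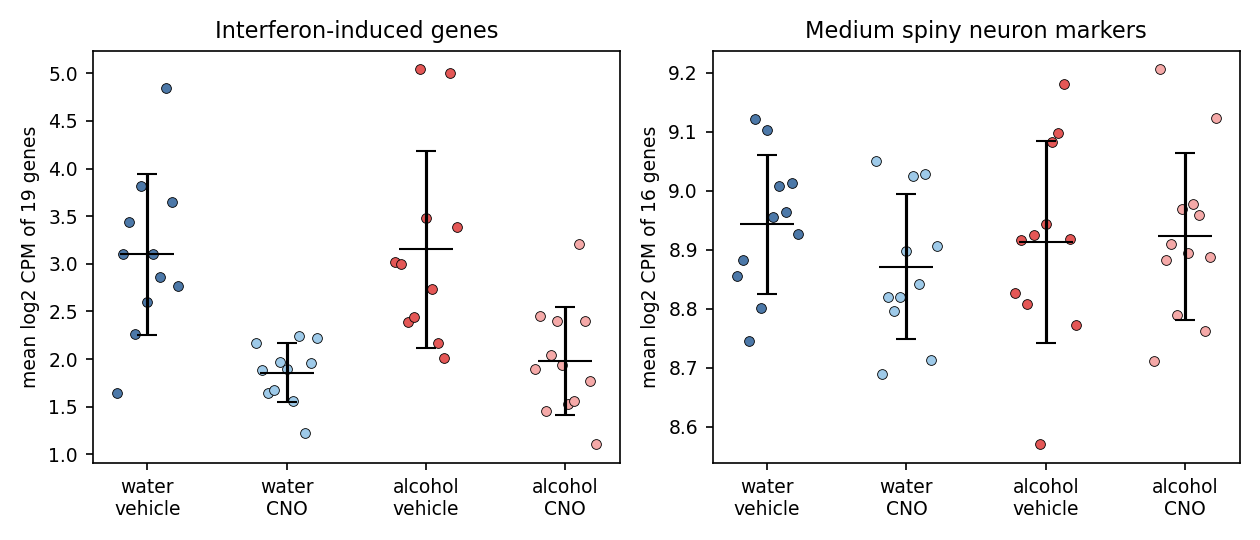
Mean log2 CPM per library of 19 interferon-induced genes (left) and 16 medium spiny neuron markers (right), by group. Points are mice and bars are the mean with SD. The interferon score averages 1.86 in water CNO and 3.10 in water vehicle mice.

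The 138 genes lower with CNO in alcohol drinkers and the 11 lower in water drinkers shared 8 genes, against 0.0958 for independent lists of these sizes. That value treats genes as independent of each other, and the overlap was not tested with random groupings. It therefore does not measure how likely 8 shared genes are by chance. The contrasts share no library, although the model shares 1 spread per gene. Of the 138 genes, 131 had negative log2 fold changes in water drinkers, with a median of -0.76 against -1.92 in alcohol drinkers, and 50 had an unadjusted p under 0.05 there.

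Alcohol was compared with water under vehicle to describe expression after alcohol drinking alone. Slpi, a protease inhibitor, and several genes of MHC class II were among the genes with the smallest p values and had positive log2 fold changes, though none passed. H2-Ab1 had a log2 fold change of 3.43 ± 0.79 (adjusted p = 0.224), H2-Aa 3.28 ± 0.80 and Ciita, the regulator of MHC class II genes, 1.31 ± 0.30. Slpi had 3.50 ± 0.76 (adjusted p = 0.19). H2-Aa averaged 32.1 CPM ± 78.7 (SD, n = 11) in alcohol vehicle and 3.34 CPM ± 3.35 (n = 11) in water vehicle mice, with medians of 2.04 and 1.34 CPM. The log2 fold change was 0.05 for H2-Ab1 and -0.14 for H2-Aa without alcohol vehicle replicates 5 and 10.

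With edgeR 0 genes passed for alcohol under vehicle, 1326 had an unadjusted p under 0.05, and DESeq2 called 3 and voom 0. The smallest adjusted p was 0.15. Of 14 antigen presentation genes 0 passed over all genes and 12 when adjusted over the list alone, with a median of 1.24 and adjusted p = 0.816 with an estimated correlation. Without alcohol vehicle replicates 5 and 10 the camera direction of this list turned to lower (adjusted p = 0.104), and the interferon list was lower (adjusted p = 4.79e-06, and adjusted p = 0.609 with an estimated correlation). That fit kept water vehicle replicate 9, whose interferon score of 4.84 was near the 5.04 and 5.00 of the mice left out. All 15 oligodendrocyte genes were positive, with a median of 0.15 (camera adjusted p = 2.02e-07, and adjusted p = 0.701 with an estimated correlation). Cldn11, a protein of myelin tight junctions, had 0.26 ± 0.07 (adjusted p = 0.271). Of 40 respiratory chain genes 37 were negative, with a median of -0.05 and adjusted p = 0.816 with an estimated correlation.

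Alcohol was also compared with water in mice that had received CNO. Zfp622 had a log2 fold change of -0.20 ± 0.04 (adjusted p = 0.478) and Emc6 -0.16 ± 0.04. With edgeR 0 genes passed, 1031 had an unadjusted p under 0.05, and DESeq2 called 0 and voom 1. Of 17 immediate early genes, which neurons switch on with activity, 15 were negative with a median of -0.12 and adjusted p = 0.84 with an estimated correlation. Of 15 glucocorticoid-induced genes 14 were negative (median -0.10, adjusted p = 0.31 with an estimated correlation). Ddit4, induced by glucocorticoids, had -0.19 ± 0.05 (adjusted p = 0.701). Of 40 respiratory chain genes 38 were negative, with a median of -0.05 and adjusted p = 0.864 with an estimated correlation.

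Whether the response to CNO differed between alcohol and water drinkers was tested as an interaction. With edgeR 0 genes passed, 496 had an unadjusted p under 0.05, and DESeq2 and voom called 0. The smallest adjusted p was 0.983. Slpi had an interaction of -4.05 ± 1.05, Plin4, a lipid droplet protein, -0.68 ± 0.22 and Smad7 -0.20 ± 0.06. The interferon list had a median of 0.01 for the interaction, with camera adjusted p = 0.872. Without alcohol vehicle replicates 5 and 10 it was positive (camera adjusted p = 9.18e-07, and adjusted p = 0.74 with an estimated correlation), so the value near 0 depends on which mice are kept. That fit kept water vehicle replicate 9, whose interferon score of 4.84 was near the 5.04 and 5.00 of the 2 mice left out. With replicate 9 also out, the list medians for CNO were -0.72 in alcohol and -1.07 in water drinkers, and camera was not run.

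Averaged over treatments, alcohol was compared with water in all mice. Pdpr had a log2 fold change of 0.19 ± 0.04 (adjusted p = 0.193), Hmbox1 0.28 ± 0.06 and Grin2b, a subunit of the NMDA receptor, 0.39 ± 0.14 (adjusted p = 0.289). With edgeR 0 genes passed, 1900 had an unadjusted p under 0.05, DESeq2 called 11 and voom 6. All 8 ependymal markers were negative (median -0.34, adjusted p = 0.831 with an estimated correlation), with Ccdc153 at -0.81 ± 0.28. All 11 astrocyte markers were positive (median 0.04, adjusted p = 0.831 with an estimated correlation), with Fgfr3 at 0.10 ± 0.03.

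The series title speaks of CNO stimulation acting against changes tied to alcohol, and the direction of the contrasts was compared across genes. The differences of group means for alcohol under vehicle and for CNO in alcohol drinkers had a Pearson correlation of -0.48 across 15852 genes, which are not independent replicates. Both contrasts hold the alcohol vehicle group with opposite signs. Unchanged groups simulated from these libraries gave a mean correlation of -0.50, ranging from -0.82 to -0.03. With the alcohol vehicle mice split into separate sets the mean was -0.03 over 100 splits, ranging from -0.26 to 0.46, and 0.17 among genes with an unadjusted p under 0.05 for alcohol. The correlation was -0.17 without alcohol vehicle replicates 5 and 10, and with the split it was 0.23 on average, ranging from 0.07 to 0.45.

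Chrm3, the mouse M3 muscarinic receptor gene and counterpart of the injected human receptor, ranged from 15.8 to 241 CPM across libraries. It averaged 99.1 CPM ± 48.4 (SD, n = 12) in alcohol CNO, 139 CPM ± 59.3 (n = 11) in alcohol vehicle, 103 CPM ± 40.2 (n = 11) in water CNO and 135 CPM ± 53.3 (n = 11) in water vehicle mice. Its log2 fold change for CNO averaged over fluids was -0.43 ± 0.20 (adjusted p = 0.493). Chrm1, chosen after its values were seen, ranged from 168 to 234 CPM.

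**Figure D4:**
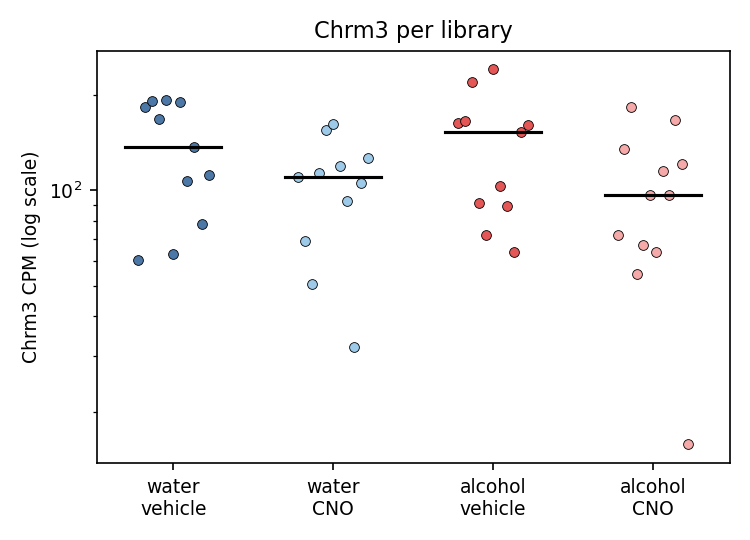
Chrm3 in each library, in CPM on a log axis, by group. Points are mice and lines are group medians. Values run from 15.8 to 241 CPM.

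Of the genes named most, in GRCm38 coordinates, Isg15 is on chromosome 4 from 156199424 to 156200818, Irf7 on chromosome 7 from 141262706 to 141266481, Cxcl10 on chromosome 5 from 92346638 to 92348889 and Cd74 on chromosome 18 from 60803848 to 60812652. Chrm3 is on chromosome 13 from 9875486 to 10360847.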

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

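Several tests in this part were chosen only after the result they concern was seen: those that leave out immune-rich libraries, those that adjust for Chrm3 or the no-feature share, and the lymphocyte score without Ccl5. The full lymphocyte score was chosen after the interferon result was seen but before its own outcome was known; how a count under 10 would be labelled for it was changed after that outcome, to match the wording set beforehand.

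Gene lists whose response to CNO differed between alcohol and water drinkers by the preset-correlation camera test of the interaction were set apart, 11 in all. Antigen presentation genes had a median interaction of -1.22 and reactive astrocyte genes -0.43. Oligodendrocyte genes had -0.21, heat shock and endoplasmic reticulum stress genes -0.19, glucocorticoid-induced genes -0.17, immediate early genes -0.11, oligodendrocyte precursor markers -0.10 and cholesterol synthesis genes -0.0767. D1 neuron markers had 0.13, D2 neuron markers 0.10 and general medium spiny neuron markers 0.0714. None of the 11 held with an estimated correlation, where the smallest adjusted p was 0.0545, for the glucocorticoid-induced genes. Without alcohol vehicle replicates 5 and 10, 6 of the 11 lost the camera call: D1 neuron markers (adjusted p = 0.0896), D2 neuron markers (0.106), general medium spiny neuron markers (0.121), oligodendrocyte precursor markers (0.0986), and antigen presentation (0.129) and reactive astrocyte genes (0.654), both of which turned to a positive direction. No single gene passed the edgeR interaction test.

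Random groupings asked whether chance can be excluded for each count, with 100 groupings including the real one. For CNO in alcohol drinkers 5 of 100 gave at least 138 genes and the highest other gave 1513, so chance cannot be excluded. For CNO in water drinkers 3 of 100 gave at least 11 (highest other 144). For CNO averaged over fluids 2 of 100 gave at least 141 (highest other 1127). Both shares are under 0.05, but they were not adjusted for the number of counts tested in this way. The groupings also ignored the S-number blocks, so chance is not excluded for either count. Groupings that call several times the real count point to a structure among the samples, whose source was not tested. For the counts of 0 this test cannot decide anything, since every grouping gives at least 0 genes and 100 of 100 was fixed in advance. The highest other counts were 258 for alcohol under vehicle, 2 for alcohol under CNO, 3 for the interaction and 3 for alcohol averaged over treatments. For lists passing camera, chance cannot be excluded in any of the 4 contrasts tested, and the interaction and the averaged contrasts were not tested in this way: 39 of 100 groupings gave at least the 11 lists of alcohol under vehicle (highest other 20), 28 the 13 of CNO in alcohol drinkers (21), 7 the 15 of CNO in water drinkers (19) and 54 the 8 of alcohol under CNO (14).

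The lower interferon-induced genes under CNO may reflect the treatment, the tissue of a few mice, or immune cells that entered it. Without alcohol vehicle replicates 5 and 10 and water vehicle replicate 9, 17 of the 19 genes stayed called and the median moved from -1.41 to -0.88. Within alcohol drinkers alone 0 were called, with a median of -0.72. Within water drinkers 11 were called against 6, although the median shrank from -1.28 to -1.07. These counts also depend on the spread shared by all libraries, so they do not measure how much those mice carried. The medians stayed below 0, so those mice alone do not account for the whole fall, and their part in it stays open. Chrm3 counts and the share of reads outside genes are argued against as whole causes. Averaged over fluids, 18 and 19 genes were called after each adjustment, with medians of -1.33 and -1.39. Centred within groups, Chrm3 had a Pearson r of 0.290 with the interferon score (permutation p = 0.0466, adjusted p = 0.105). Chrm3 counts were not checked as a measure of the injected receptor, so the amount of that receptor stays open. Within alcohol and water drinkers 11 and 1 were called with Chrm3, and 4 and 2 with the share of reads, against 14 and 6 unadjusted. The medians there were -1.47 and -1.19 with Chrm3 and -1.56 and -1.34 with the share of reads, against -1.54 and -1.28. With surrogate variables, an alternative chosen before the data were examined, 7 genes passed averaged over fluids and 6 of them were lower. At most 6 of the 19 could then be called, so structure among the samples stays open. Lymphocytes stay open: adjusting for the lymphocyte score left 0 called (median -0.45), but that list holds Ccl5, which interferon itself induces, and without Ccl5 12 were called (median -0.97). Cell entry and interferon signalling respond to each other, so these adjustments may also remove part of a treatment effect, and CNO as the cause remains untested beyond the group comparison. Every mouse received the receptor virus, so an action of CNO through the receptor cannot be told apart from other actions of CNO. CNO was last given in week 5, and vehicle followed in week 6.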

How the results depend on the processing

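The immune-rich, no-feature, Chrm3 and leave-one-out alternatives were chosen only after the results were seen. For CNO in alcohol drinkers 138 genes became 223 at an adjusted p under 0.1, 221 with no filter, 19 with the no-feature share, and 0 with S-number block, surrogate variables, outlying libraries left out, voom with sample weights, only the 2 groups compared, immune-rich libraries left out, or these and water vehicle replicate 9; leaving out 1 library gave 0 (alcohol vehicle replicate 5) to 240 (replicate 4), with 51 without replicate 10, 220 without 8, 230 without 9 and 88 without alcohol CNO replicate 12. For CNO in water drinkers 11 became 4 with block, 25 in DESeq2, 0 in voom, 24 with only the 2 groups, 55 and 29 without the immune-rich libraries alone and with water vehicle replicate 9, 5 with the no-feature share and 4 with Chrm3; leaving out 1 library gave 1 (water vehicle replicate 9) to 14, with 6 without water CNO replicate 3, 4, 5 or 9 or water vehicle replicate 5, and 7 without water CNO replicate 1, 2 or 7 or water vehicle replicate 3. For CNO averaged over fluids 141 became 7 with surrogate variables, 24 without outlying libraries, 47 in voom, 73 without the immune-rich libraries and 61 also without water vehicle replicate 9; leaving out 1 library gave 98 to 204. Counts of 0 became 3 in DESeq2 for alcohol under vehicle, 13 with surrogate variables and 1 in voom for alcohol under CNO, and for alcohol averaged over treatments 4 with block, 8 with surrogate variables, 11 in DESeq2, 6 in voom and 98 with the no-feature share, while the interaction stayed at 0 in every alternative run. Lists passing in the fit to all libraries were 0 with an estimated correlation in all 4 contrasts. In fry they were 0, 0 and 0 for alcohol under vehicle, CNO in alcohol drinkers and alcohol under CNO, and 2 for CNO in water drinkers. Without the immune-rich libraries the lists passing camera with the preset correlation for CNO in alcohol drinkers went from 13 to 6. With an estimated correlation 0 passed there. For CNO in water drinkers 3 passed with an estimated correlation without those libraries: interferon (adjusted p = 0.00848), lymphocyte, which holds Ccl5 (0.00848), and oligodendrocyte precursor markers (0.0254). Serping1 in CNO-treated alcohol drinkers reversed to 0.0024 and H2-Eb1 to 0.16 with surrogate variables. The correlation of the alcohol and CNO differences, -0.48, moved to -0.0254 with alcohol vehicle split and -0.17 without the immune-rich libraries, and reversed to 0.17 with the split among genes with unadjusted p under 0.05 and to 0.23 with the split and those libraries out. The move of the correlation with the split goes with the shared alcohol vehicle group. Simulated unchanged groups that shared 1 group gave a mean of -0.50, ranging from -0.82 to -0.03. The immune-rich libraries are not in the water groups. Leaving them out can change the water results only through the filter, scaling and spread taken over all libraries. Which of these acted, and the cause of the other changes, was not tested. The 41 calls of named genes, set against 8 alternatives each, were kept in 166 of 328 comparisons, lost in 160 and reversed in 2; for CNO in alcohol drinkers 43 of 144 were kept, in water drinkers 55 of 80 and averaged over fluids 68 of 104. Named genes that had not passed gained a call in 33 of 2493 comparisons.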

Other observations

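The tests in this part on the no-feature share, tube order and the Chrm3 counts were chosen only after the results were seen; the block test and the random groupings were chosen before their outcome was known.

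Synapse and channel genes had more positive than negative log2 fold changes with CNO averaged over fluids, with medians near 0. Of 28 glutamate receptor and scaffold genes 21 were positive, with a median of 0.03 and adjusted p = 0.438 with an estimated correlation. Of 26 ion channel genes 23 were positive (median 0.04, adjusted p = 0.448 with an estimated correlation), with Kcna2, a potassium channel, at 0.10 ± 0.04. Of 22 opioid, dopamine and stress peptide genes 17 were positive (median 0.08, adjusted p = 0.14 with an estimated correlation), with Npy2r, a receptor of neuropeptide Y, at 0.19 ± 0.07. None of these genes passed singly, and without alcohol vehicle replicates 5 and 10 the glutamate (adjusted p = 0.147) and ion channel lists (adjusted p = 0.0835) did not pass camera with the preset correlation either.

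Genes that differed by fluid, averaged over treatments, appeared when the no-feature share was a covariate: 98 passed, 53 higher and 45 lower with alcohol, against 0 without it. All 98 had the same sign without the covariate. The median size of their log2 fold changes was 0.146 with it and 0.116 without, and the median SE 0.0347 with it and 0.0465 without. This covariate was 1 of 5 alternatives of libraries or covariates added after the data were seen and applied to each count of genes, and the groupings below do not allow for that choice. Slc18a2, a transporter of monoamines into vesicles, had -0.30, Pdgfra 0.15, Gabra2, a GABA receptor subunit, 0.17 and Ntrk2, the receptor of Bdnf, 0.12, chosen after their values were seen. Of 100 groupings 1, the real one, gave as many (highest other 2), and with S-number block added 347 passed, which argues against the block as the source. Tube order could be the source and cannot be told apart from fluid, since 0 alcohol tubes lie within the range of the water tubes.

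Chrm3 counts varied many-fold within groups and may include reads of the injected human receptor, a hypothesis left open. The within-group SD of Chrm3 was 0.75 on the log2 scale, and only 0.105% of 1908 genes of similar level had one as large, against 48.7% for Chrm1, 27.2% for Chrm2, 14.4% for Chrm4 and 20.3% for Chrm5 among genes of their own levels, the 4 being chosen after the result for Chrm3 was seen; this restates the spread for which Chrm3 was picked and gives no support to the hypothesis. The share of reads outside genes is argued against over all groups but stays open in alcohol CNO mice, where the Pearson correlation was -0.607; centred within groups over all mice it was -0.181 (permutation p = 0.239, adjusted p = 0.429) and the Spearman correlation -0.209 (permutation p = 0.184, adjusted p = 0.331), and Pearson r was -0.211 without the 2 farthest samples, among 9 relations computed. The strongest relation of Chrm3 was with Gfap, an astrocyte gene, with Pearson r = 0.514 (permutation p = 0.00055, adjusted p = 0.00248) and Spearman rho = 0.486 (permutation p = 0.00127, adjusted p = 0.00572), and r = 0.318 without the 2 farthest samples; by group r was 0.752 in alcohol CNO, 0.0566 in alcohol vehicle, 0.856 in water CNO and 0.457 in water vehicle mice. The hypothesis would be tested by aligning the reads to the human CHRM3 and mCherry sequences, which was not done because the files hold only counts.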
